A study of Homo sapiens with 6 samples.

How the data were processed

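RNA sequencing was done on xenograft tumours of HT-29, a human colorectal cancer cell line, from an untreated control group and from a group given 60 mJ extracorporeal shock waves, which are pressure pulses applied from outside the body. Both groups were taken at day 15 and held 3 samples each, and the labels give all 6 samples the same batch value. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a SMARTER mRNA-seq kit. Groups were read from the treatment labels, and replicate numbers from the titles. Nothing in the labels says that the samples of a group came from separate animals, so p-values measure only the spread between these samples.

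The authors deposited 1 table of normalized expression with 131516 rows, 1 per transcript, and a column for each of the 6 samples. Its unit is not named in the sources used here. The deposited values were taken as FPKM, fragments per kilobase of transcript per 1000000 reads, because multiplying them by transcript length gave whole numbers of reads. Over values worth 0.5 to 100 reads, 99.64 to 99.70% lay within 0.05 of a whole number. The genome build was hg38 per the submitters' processing notes. The aligner, the assembler and the quantification program are not given in the sources used here, and neither is whether reads of the host animal were removed.

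Of the rows, 116485 carry an Ensembl transcript and gene identifier and a symbol, and 15031 are assembled transcripts with neither gene nor position. Lengths and GC content came from GENCODE release 29 for 116423 annotated transcripts, and 62 had none there. Assembled transcripts held 9.75 to 11.4% of the summed FPKM of a library and stayed out of the gene tests. FPKM of annotated transcripts were summed per gene, giving 29385 genes. Genes with at least 1 FPKM in at least 3 of the 6 samples were tested, which left 13451. Coordinates are those of the table on hg38, counted from 1, and span all listed transcripts of a gene. No sample column of the table was left unused, and no 2 samples held identical values.

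The recovered totals ran from 48300000 to 58540000 reads per library, of which 41020000 to 50990000 lay on annotated transcripts. The values show that reads were placed whole on single transcripts, so a gene's FPKM also depends on which of its transcripts was given the reads, through the length of that transcript. Genes that share sequence with a paralog or pseudogene, such as those of ribosomal proteins, are uncertain for the same reason, as are overlapping and antisense genes.

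The comparison used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with a mean-variance trend and no covariate, and Benjamini-Hochberg adjusted p with a threshold of 0.05. Log2 changes are on that scale, which understates the change of genes with low values. Lists of genes for 38 programmes or quality measures and for 10 other cell types were fixed before the data were examined. Of 1190 entries, 1111 matched a gene of the table, 35 of them through a current symbol. The 42 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 42 lists. Camera with an estimated correlation and the rotation test fry were alternatives. Summed values and the mean level of each list per library were compared with an exact two-sided permutation test over 20 arrangements, whose smallest p is 0.1.

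The genes named in the text follow a rule fixed beforehand. It takes up to 8 genes per direction past the threshold with separated groups and a mean of at least 1 FPKM, and up to 4 passing members of each called list. Where no member passes, the 2 members with the smallest p in the direction of the list are given as values. A fixed panel is given whatever its result, with 18 genes, and 1 further gene of it is not reported here. Because fewer than 6 genes passed in each direction, the 6 nameable genes with the smallest p per direction are given as values that did not pass. These too had a mean of at least 1 FPKM. Genes used to infer sex are not named, nor are identifiers without a gene symbol.

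Alternatives fixed beforehand were limma without the trend, quantile normalization, upper-quartile scaling, no filter, a filter of 5 FPKM, a pseudocount of 0.1, the replicate number as a block, each replicate left out, a 2-fold threshold, and a fit without mitochondrially encoded, haemoglobin and other-cell genes. Others were chosen after seeing the data. These were limma voom on the recovered reads of 14636 genes with at least 1 read per 1000000 in 3 samples, transcripts in place of genes, sample quality weights, removal per library of a trend on transcript length or on GC content, and scaling of each library to the same sum.

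The gene and list tests were tested on simulated data in which 200 of 13451 genes differed between 3 and 3 samples with the measured means and spreads, over 20 runs. The gene test found 55.3% of the genes with a log2 change of 1, 95.1% of those with 2, 99.1% of those with 3 and 99.6% of those with 4, with a median of 11.5 false calls per run. The changed genes were drawn only from those with higher FPKM, so these shares do not hold for genes with low values. Noise was drawn for each gene alone, with no library standing apart as a whole. The list test called a list shifted by 0.5 in 100% of the runs and 0.12% of the unshifted lists, where simulated genes were independent of each other. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the plots.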

Results

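The transcriptomes of 6 samples of HT-29 xenograft tumours were compared, 3 from untreated controls and 3 from the group given 60 mJ shock waves, all at day 15. Each sample is called a tumour below, although the labels do not say that the samples came from separate animals. HT-29 is an established human colorectal cancer line, and a xenograft is a tumour grown from such cells in a host animal. The comparison asks which transcripts differ in abundance between shock wave and control tumours, and the title of the series places it in a study of colorectal cancer proliferation and growth. Library totals recovered from the values were 52170000, 55490000 and 48300000 reads in the controls and 55200000, 55230000 and 58540000 in the shock wave group. Between 12794 and 13440 genes reached 1 FPKM in a library.

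Among the genes that could be named, ST3GAL2, MTHFD2 and PDXK had the smallest p. These were lower in every shock wave tumour than in every control, but none of the 13451 genes passed the threshold in either direction. PDXK, the kinase that makes pyridoxal phosphate from vitamin B6, measured 44.5 ± 3.39 FPKM in controls (SD, n = 3) and 9.57 ± 3.68 in shock wave tumours (SD, n = 3). MTHFD2, a mitochondrial enzyme of folate metabolism, measured 20.1 ± 3.17 and 5.66 ± 0.594 FPKM. ST3GAL2, a sialyltransferase, measured 14.6 ± 0.563 and 3.64 ± 0.733 FPKM. Limma gave 0 genes higher and 0 lower at an adjusted p of 0.05, with 933 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.134. All 3 shock wave tumours lay above all 3 controls for 1042 genes and below them for 1167. Together these were 16.4% of the genes tested, where chance gives 10%. Genes are not independent of each other and the share was not computed for other splits, so it is not a test of an excess. Limma voom on the recovered reads, chosen after seeing the data, called 1 gene, PDXK, with a log2 change of -3.96 in reads (SE 0.16, adjusted p = 0.00299). Leaving out shock wave replicate 2 gave 1 gene higher (AC068580.4) and 4 lower (PDXK, SEC16A, MBNL3 and NOL4L), and leaving out shock wave replicate 3 gave 0 higher and 1 lower (GTF2F2), these genes other than PDXK being named after their values were seen.

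Of the lower nameable genes with the smallest p, PDXK lies on chromosome 21 at 43719094 to 43762307 (hg38, plus strand, protein-coding). It had a log2 change of -2.16 (SE 0.24, limma adjusted p = 0.170). Its difference lay in 1 transcript, ENST00000291565, at 38.4, 34.5 and 39.4 FPKM in controls and 1.89, 0.998 and 1.01 in shock wave tumours, while its other transcripts summed to 8.57, 6.13 and 6.55 against 5.59, 12.8 and 6.39. ST3GAL2 lies on chromosome 16 at 70375978 to 70439237, minus strand, with a log2 change of -1.76 (SE 0.18, adjusted p = 0.134). MTHFD2 lies on chromosome 2 at 74198562 to 74217565, plus strand, with a log2 change of -1.66 (SE 0.17, adjusted p = 0.134). The other 3 each had an adjusted p of 0.179. TMEM184C, on chromosome 4 at 147617383 to 147672044, measured 7.61 ± 1.77 FPKM in controls and 1.42 ± 0.344 in shock wave tumours. C18orf32, on chromosome 18 at 49477250 to 49487252, measured 23.7 ± 2.64 and 8.97 ± 1.26 FPKM. SNTB1, which encodes the adaptor protein beta-1-syntrophin and lies on chromosome 8 at 120535745 to 120813273, measured 25.7 ± 7.20 and 6.15 ± 0.736 FPKM.

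Among the nameable genes with higher values, SLC35A2, the UDP-galactose transporter of the Golgi, had the smallest p. It lies on chromosome X at 48903180 to 48911958, minus strand, and measured 16.8 ± 0.433 FPKM in controls and 33.1 ± 1.67 in shock wave tumours, a log2 change of 0.94 (SE 0.12, limma adjusted p = 0.179). PPT1, a lysosomal thioesterase on chromosome 1 at 40071461 to 40097727, measured 24.5 ± 1.32 and 50.6 ± 12.1 FPKM. TBC1D1, a GTPase-activating protein of glucose transporter traffic on chromosome 4 at 37891087 to 38139175, measured 2.77 ± 1.61 and 16.1 ± 5.20 FPKM. Here too 1 transcript, ENST00000446803, held the difference (at most 0.094 FPKM in controls and 19.1, 13.02 and 9.53 in shock wave tumours), and the other transcripts of TBC1D1 summed to 1.93, 1.71 and 4.54 against 2.97, 1.09 and 2.73. CD99L2, on chromosome X at 150766337 to 150898816, measured 0.887 ± 0.631 and 5.54 ± 2.26 FPKM. NAA35, a subunit of an N-terminal acetyltransferase on chromosome 9 at 85941146 to 86022298, measured 0.171 ± 0.124 and 3.41 ± 1.79 FPKM. The small nucleolar RNA SNORA21, on chromosome 17 at 38852863 to 38852994, rested on 1 read in each control and on 25, 14 and 34 reads in the shock wave tumours. Their adjusted p ran from 0.245 for SNORA21 to 0.530 for PPT1, NAA35 and CD99L2.

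**Figure D1:**
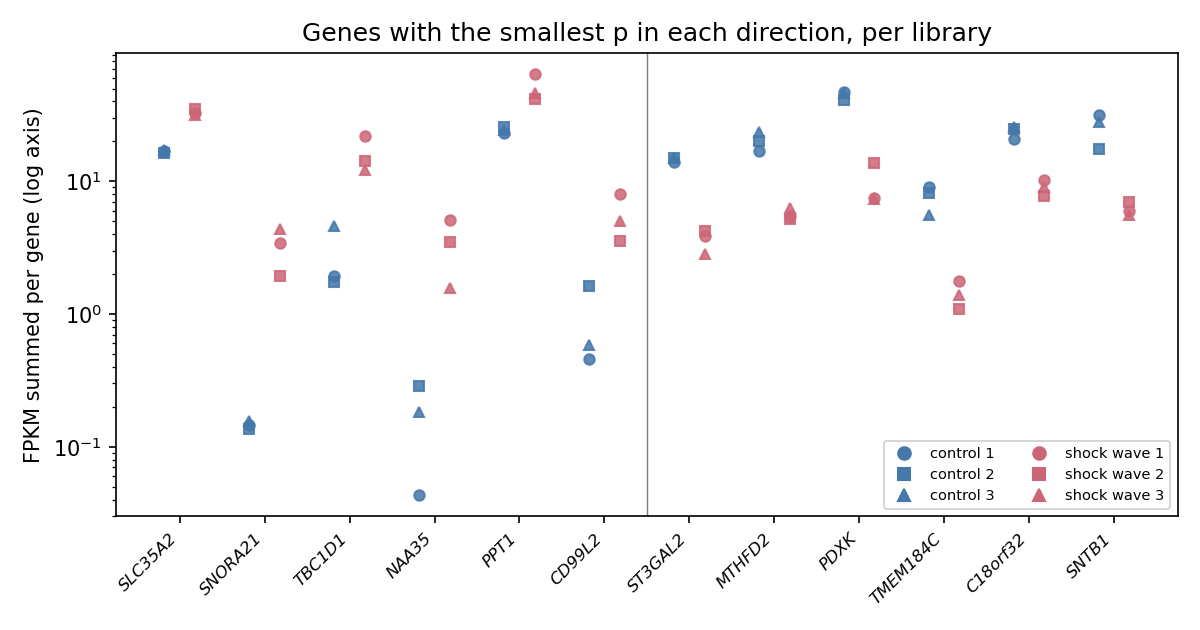
FPKM summed per gene (log axis) in each of the 6 libraries for the nameable genes with the smallest p. The 6 higher in shock wave tumours are left of the line and the 6 lower are right of it. Circles, squares and triangles are replicates 1, 2 and 3, blue for control and red for shock wave. The 3 shock wave values lie on 1 side of the 3 controls for each of these genes, and none had an adjusted p under 0.134.

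Genes of nuclear-encoded oxidative phosphorylation, of the ribosome and of the interferon response were higher as lists in shock wave tumours relative to the other genes. Of 43 tested oxidative phosphorylation genes, 39 had a positive log2 change and 0 passed alone, with a median of 0.29 and a camera adjusted p of 2.95e-08 (adjusted p = 0.771 with an estimated correlation). ATP5MC3, a subunit of ATP synthase, measured 33.0 ± 4.84 FPKM in controls and 47.7 ± 0.985 in shock wave tumours, and NDUFA2, a subunit of complex I, 58.0 ± 1.75 and 87.5 ± 24.1. Of 55 ribosomal protein genes, 50 had a positive change and 0 passed alone, with a median of 0.33 and a camera adjusted p of 5.19e-08 (adjusted p = 0.771 with an estimated correlation). RPL18 measured 294 ± 152 and 637 ± 66.7 FPKM, and RPL32 measured 129.6 ± 18.4 and 213 ± 58.8. The mean log2 level of the ribosomal list relative to controls was 0.82 in shock wave replicate 3, against 0.20 and 0.02 in replicates 1 and 2. Without replicate 3 the ribosomal median was 0.07 (camera adjusted p = 0.0283) and that of oxidative phosphorylation 0.17 (adjusted p = 0.000221). With quantile normalization they were 0.10 (adjusted p = 0.0256) and 0.16 (adjusted p = 0.000518). With the length trend removed, a setting chosen after seeing the data, they were 0.19 (adjusted p = 0.000568) and 0.18 (adjusted p = 1.2e-05). Related lists were not called with all 6 libraries. Mitochondrially encoded oxidative phosphorylation (10 genes, 7 negative) had a median of -0.05 (camera adjusted p = 0.980). MYC and ribosome biogenesis (30 genes, 17 positive) had a median of 0.05 (adjusted p = 0.384) and was called as higher without shock wave replicate 3.

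Of 33 interferon response genes, 28 had a positive change, 8 had an unadjusted p under 0.05 and 0 passed the adjusted threshold, with a median of 0.33 and a camera adjusted p of 6.70e-05 (adjusted p = 0.771 with an estimated correlation). MX2, an antiviral GTPase, measured 2.56 ± 1.26 FPKM in controls and 8.54 ± 4.51 in shock wave tumours. ISG20, an exonuclease, measured 11.5 ± 1.96 and 17.1 ± 2.30. The list was highest in shock wave replicate 1, with a mean log2 level relative to controls of 0.83, against 0.24 in replicate 2 and -0.10 in replicate 3. Without replicate 1 its call was lost (median 0.13, camera adjusted p = 0.102), and without replicate 3 the median was 0.48. Sample quality weights, chosen after seeing the data, gave 0.70 (adjusted p = 1.27e-10), with a weight of 2.47 for replicate 1 and 0.274 for replicate 3. The list of antigen presentation genes, 12 of 16 with a positive change, had an adjusted p of 0.0514 and was called in several alternatives, among them without shock wave replicate 3 (adjusted p = 0.0146).

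Members of PI3K-AKT-mTOR signalling, of RAS-MAPK signalling and of integrin and focal adhesion were lower as lists. Of 23 PI3K-AKT-mTOR genes, 21 had a negative change, with a median of -0.33 and a camera adjusted p of 0.00111 (adjusted p = 0.771 with an estimated correlation). AKT1, a serine-threonine kinase, measured 64.5 ± 1.53 FPKM in controls and 35.0 ± 5.47 in shock wave tumours, and was the 1 member past the threshold when adjusted over the list alone. RICTOR, a subunit of mTOR complex 2, measured 8.85 ± 2.99 and 3.58 ± 1.55. Of 24 RAS-MAPK genes, 20 had a negative change, with a median of -0.24 and a camera adjusted p of 0.00785 (adjusted p = 0.771 with an estimated correlation). MET, the receptor of hepatocyte growth factor, measured 64.9 ± 12.5 and 28.5 ± 4.34 FPKM and was the 1 member past the threshold adjusted over the list alone. BRAF measured 5.59 ± 1.16 and 3.34 ± 0.930. Of 30 integrin and focal adhesion genes, 24 had a negative change, with a median of -0.24 and a camera adjusted p of 0.0107 (adjusted p = 0.771 with an estimated correlation). FLNA, an actin cross-linker, measured 120.8 ± 8.76 and 72.8 ± 32.1 FPKM, and PARVA 7.79 ± 0.516 and 4.72 ± 2.09. With the length trend removed, a setting chosen after seeing the data, these 3 calls were lost (adjusted p = 0.0807, 0.0807 and 0.0719), and without shock wave replicate 3 the medians were -0.15, -0.11 and -0.12. In these 3 lists 0 members passed over all genes, where the limma adjusted p was 0.504 for AKT1 and 0.422 for MET. In the oxidative phosphorylation, ribosomal, interferon and adhesion lists 0 passed adjusted over the list alone. The DNA repair list and the pericyte and smooth muscle list, which were not called, each had 1 member that did. Passing within a list therefore does not set the called lists apart.

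**Figure D2:**
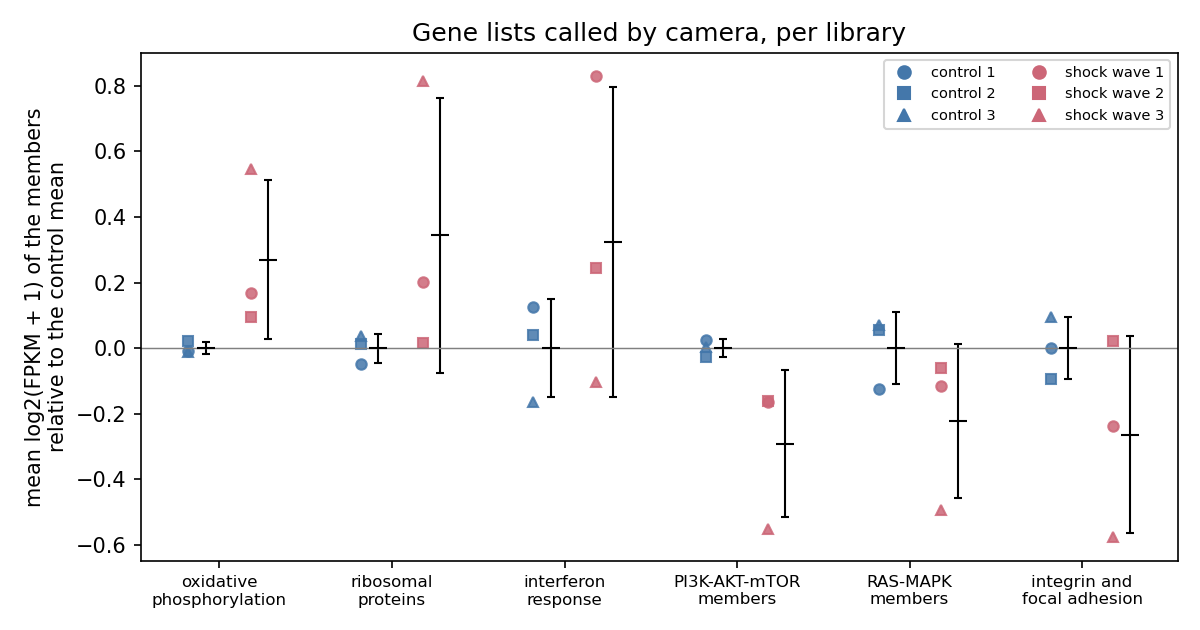
Mean log2(FPKM + 1) of the members of each called list in each library, relative to the control mean. Circles, squares and triangles are replicates 1, 2 and 3, blue for control and red for shock wave, and black bars are the mean ± SD of 3 libraries. Shock wave replicate 3 lies farthest from the controls in 5 of the lists, and replicate 1 in the interferon response list, at 0.83.

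These list calls depended on how correlation between genes was treated. With an estimated correlation 0 of the 42 lists passed, and with fry, which asks whether the members move one way without comparing them with other genes, 0 passed (adjusted p = 0.651 for each of the 6). The integrin and focal adhesion call was also lost without control replicate 3 (median -0.20, adjusted p = 0.0866) and without shock wave replicate 1 (median -0.29, adjusted p = 0.107), where the median stayed near or beyond the -0.24 of all 6 libraries. Median transcript lengths were 1086 bases in the oxidative phosphorylation list, 937 in the ribosomal, 2449 in the interferon, 4404 in the PI3K-AKT-mTOR, 3661 in the RAS-MAPK and 3878 in the adhesion list. In shock wave replicate 3 log2 levels fell by 0.20 per doubling of transcript length, against slopes of -0.07 and 0.02 in shock wave replicates 1 and 2 and 0.03 to 0.05 in the controls.

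**Figure D3:**
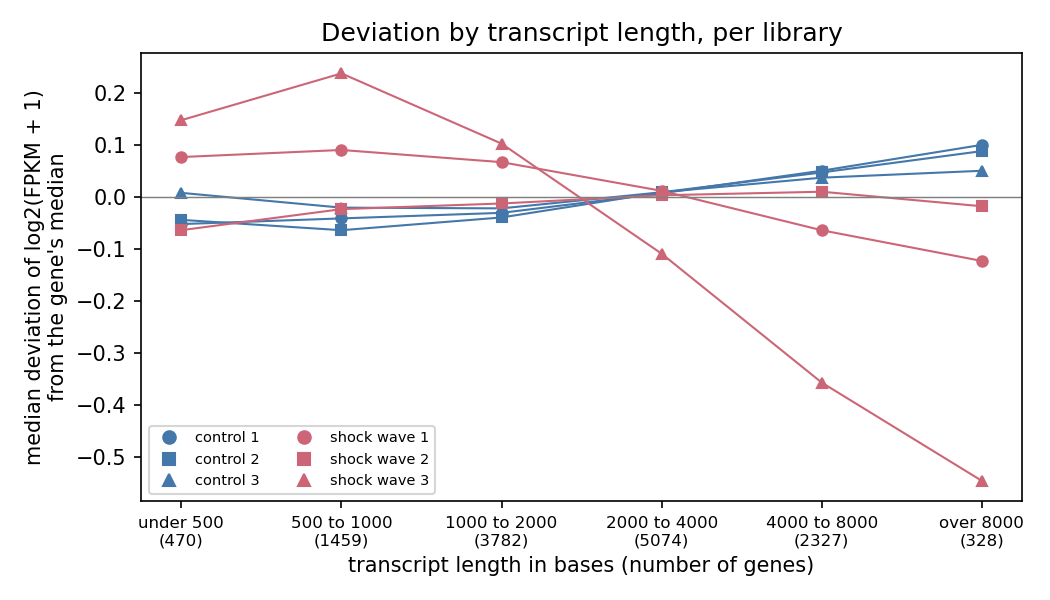
Median deviation of log2(FPKM + 1) from each gene's median over the 6 libraries, by transcript length in bases, for 13440 genes. Lines are libraries, blue for control and red for shock wave, with circles, squares and triangles for replicates 1, 2 and 3. Shock wave replicate 3 falls from 0.24 at 500 to 1000 bases to -0.54 above 8000.

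Proliferation genes, on which the title of the series bears, did not pass as lists with all 6 libraries. The mitosis list (30 genes, 22 with a negative change) had a median of -0.15 and a camera adjusted p of 0.147. Without control replicate 1 the mitosis list was called as lower (median -0.22, adjusted p = 0.0136), and without control replicate 2 the test placed it higher (median -0.04, adjusted p = 0.993). Both used the preset correlation, and with all 6 libraries and an estimated correlation the camera adjusted p was 0.771. The DNA replication list (39 genes, 25 negative) had a median of -0.04 and an adjusted p of 0.886. MKI67, a marker of cycling cells, measured 2.43, 9.93 and 28.4 FPKM in the 3 controls and 2.59, 5.57 and 6.60 in the shock wave tumours, a spread among controls larger than the difference of the means (limma adjusted p = 0.689). PCNA, the sliding clamp of DNA replication, measured 100.2 ± 15.2 and 123 ± 8.92 FPKM. CCND1, which encodes cyclin D1, measured 67.2 ± 6.89 and 63.4 ± 16.2, and the cell cycle inhibitor CDKN1A 61.3 ± 7.31 and 56.8 ± 18.9. MYC was high in control replicate 1 alone, at 51.6 FPKM, and lay between 6.49 and 9.66 in the other 5 libraries (adjusted p = 0.683).

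With all 6 libraries the lists of cell death and stress genes were not called either, but those of chaperones and hypoxia were called in some alternatives. The list of apoptosis effectors (31 genes) had a median of 0.09 and a camera adjusted p of 0.442, and the list of p53 targets (25 genes) a median of -0.13 and an adjusted p of 0.582. BAX measured 80.2 ± 4.17 FPKM in controls and 95.4 ± 8.99 in shock wave tumours, with an adjusted p of 0.648. BCL2, an inhibitor of apoptosis, stayed at or under 0.222 FPKM in each library. The chaperone list (27 genes, 18 with a negative change) had a median of -0.08 and an adjusted p of 0.0600. It was called as lower with quantile normalization (adjusted p = 3.58e-05), without control replicate 2 (0.0258) and without shock wave replicate 3 (0.00188). These calls used the preset correlation. With all 6 libraries the chaperone list had an adjusted p of 0.771 with an estimated correlation and 0.651 with fry. HMOX1 measured 3.39 ± 0.570 and 4.48 ± 1.09 FPKM. HSPA1A reached 2.08 FPKM in shock wave replicate 3 and at most 0.190 elsewhere. FOS measured 42.2 ± 11.2 and 35.0 ± 9.28, and VEGFA, the angiogenic growth factor, 97.2 ± 33.2 and 93.5 ± 61.9. For the hypoxia list (27 genes) the median was 0.04 and the mean 0.03 while camera placed it lower (adjusted p = 0.932). Without shock wave replicate 3 it was called as lower at the preset correlation, with a median of -0.31 (adjusted p = 4.14e-05). With all 6 libraries and an estimated correlation the hypoxia list had a camera adjusted p of 0.991.

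The epithelial and colonic markers of the panel were abundant in both groups. KRT20, a keratin of differentiated colonic epithelium, measured 665 ± 52.2 FPKM in controls and 695 ± 178 in shock wave tumours, EPCAM 383 ± 19.1 and 479 ± 105.2, and CDH1, which encodes E-cadherin, 108.3 ± 4.17 and 85.7 ± 18.8. None of these 3 passed, with adjusted p between 0.648 and 0.953. VIM stayed at or under 1.60 FPKM and the stem cell marker LGR5 at or under 0.819. The nuclear RNA MALAT1 measured 21.2 ± 1.22 and 23.5 ± 4.04 FPKM.

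Genes of other cell types were asked for because a xenograft also holds host stroma, vessels and blood. None of the lists for other cells passed. The table holds transcripts on the human build hg38, and whether host reads were removed is not given. Cells of a host animal therefore show only as far as their reads were placed on human transcripts. HT-29 cells may also express listed genes themselves, so a list that did not pass says little about host cells. Camera gave adjusted p of 0.0853 for pericytes and smooth muscle (5 genes, median -0.49), 0.582 for macrophages, 0.886 for endothelium and 0.922 for fibroblasts. Fewer than 5 members could be tested for adipocytes (4), skeletal muscle (4), skin keratinocytes (2), neutrophils (0), lymphocytes (0) and erythroid cells (0). Without control replicate 1 the pericyte and smooth muscle list was called, the 1 call among other-cell lists in any setting. COL1A1, a fibroblast collagen, measured 23.0, 5.78 and 8.24 FPKM in controls and 1.32, 9.25 and 3.45 in shock wave tumours (adjusted p = 0.648), and the most abundant haemoglobin gene, HBA1, averaged 0.233 FPKM.

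Summed FPKM per library was 482461 ± 4227 in controls and 523375 ± 43910 in shock wave tumours (SD, n = 3 each; exact two-sided permutation p = 0.2, where 0.1 is the smallest possible). The highest sum, 571671, was that of shock wave replicate 3. Its log2 levels correlated with those of the other libraries at 0.921 to 0.939 across genes, while the other 5 correlated with each other at 0.949 to 0.959, genes not being independent replicates. Mitochondrially encoded genes held 9.64 ± 0.689% of the summed FPKM in controls and 9.18 ± 1.19% in shock wave tumours (exact two-sided permutation p = 0.7).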

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

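The test on assembled transcripts and the removal of the length trend were chosen after the data were seen. The gene comparison left out the 15031 assembled transcripts without a gene name. In those data 7 of the 7441 that could be tested were higher in shock wave tumours than in controls, with 12 lower (limma adjusted p under 0.05). Of the 7 higher, the 1 with the smallest p stood at 1.81, 1.26 and 2.82 FPKM in controls and at 34.1, 36.2 and 33.3 in shock wave tumours (limma adjusted p = 0.0218). The adjustment ran over all 35958 transcripts tested, and 47 of the 28517 annotated ones were called. The true split called 66 transcripts of both kinds, and other splits of the 6 samples called 17 to 51.

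PDXK stood at 47.0, 40.7 and 45.9 FPKM in controls and 7.48, 13.8 and 7.40 in shock wave tumours, and its recovered reads at 15222, 14503 and 14381 against 1149, 1095 and 836. The size of the transcript-length trend argues against it as the cause, since its largest median deviation in a length class was -0.54. The log2 change of PDXK was -1.93 once that trend was removed, an outcome that the size of the trend fixed in advance. The difference lay in 1 annotated transcript, ENST00000291565 (limma adjusted p = 0.0107), and the other transcripts of the gene did not separate the groups. The assembled transcripts carry neither length nor position, so these data give no test of whether reads of that transcript were placed on any of them, and both that and an effect of treatment stay open.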

How the results depend on the processing

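The counts of 0 genes higher and 0 lower held under every alternative fixed beforehand except the omission of replicates, where the counts ran from 0 to 1 and from 0 to 4. With the replicate number as a block 0 genes passed (smallest adjusted p 0.652) and 9 lists did. Same-numbered samples did not deviate together (correlations of -0.01, -0.01 and 0.03, and not every sample correlated best with its own number), so the numbers are not taken as pairs. Among settings chosen after seeing the data, recovered reads gave 1 gene lower, sample weights 2 lower (ST3GAL2 and PDXK), and transcripts 23 higher and 43 lower. The 6 list calls became 12 with quantile normalization, 12 with sample weights, 10 with equal sums (which moved the median of all genes to -0.11), 3 with the length trend removed and 0 with an estimated correlation or fry, and 4 to 14 with a replicate left out. Calls of other-cell lists ran from 0 to 1. The cause of these moves was not tested, except that the estimated correlation of the 6 lists, 0.172 to 0.612, exceeds the preset 0.01.

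Some lists not called with all 6 libraries were called in such settings, among them chaperones and hypoxia (adjusted p = 0.00369 each with sample weights, and 0.00978 for chaperones with equal sums). The direction given by a test turned only for results not called with all 6 libraries in the planned test. The DNA replication median was 0.085 with sample weights and 0.0285 with the length trend removed. The hypoxia median was 0.0361 without a filter and with the block, 0.0957 on recovered reads and 0.0715 without the length trend. KRT20 was at -0.19 with quantile normalization. With a replicate left out, the log2 ranges of those that turned were mitosis -0.2199 to -0.0397, DNA replication -0.1209 to 0.0595, hypoxia -0.31 to 0.20, CCND1 -0.27 to 0.10, MYC -1.3192 to 0.0393, CDKN1A -0.4029 to 0.021, VEGFA -0.68 to 0.14 and KRT20 -0.16 to 0.17. In the settings fixed for them the other named genes kept their direction, as did the called and apoptosis lists. On recovered reads MALAT1 turned to -0.14 and VEGFA to 0.14. The difference in summed FPKM, 40914, was 39672 without mitochondrially encoded genes. Depth, at 48300000 reads or more, limits genes such as SNORA21 that rest on single reads.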

Other observations

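The transcript tests and the removal of the length trend were chosen after the data were seen, and the bounds for single libraries and for the splits after their results, while leaving out replicates and the estimated correlation were planned. More single transcripts than genes passed the threshold. Of 35958 transcripts, limma called 23 higher and 43 lower, with 2301 at an unadjusted p under 0.05. Of the 47 annotated ones, 40 belonged to genes whose own log2 change was smaller than 1. APLP2, a relative of the amyloid precursor protein, had protein-coding transcripts called in opposite directions. Its transcript ENST00000278756 stood at 71.2, 69.3 and 76.8 FPKM in controls and at most 0.039 in shock wave tumours (adjusted p = 0.00125), while ENST00000263574 stood at 3.85, 5.27 and 8.17 and then 60.5, 68.0 and 64.7 (adjusted p = 0.0254). The summed gene had a log2 change of -0.12. COPG1, a subunit of the vesicle coat, had a coding transcript at 13.5, 15.2 and 17.1 FPKM in controls and 79.2, 73.4 and 63.2 in shock wave tumours, and a retained-intron transcript at 67.6, 63.5 and 56.6 that was listed at 0, 0 and 2.59. These 2 genes, named after their values were seen, were the ones with calls both ways. Because reads were placed whole on single transcripts, an exchange of transcripts and a different placement of reads cannot be told apart here. The true split called 66 transcripts, and 1 of the 10 splits of the 6 samples, the true one, gave that many. The other splits gave 17 to 51 transcripts but 0 to 5 genes, so transcripts pass more often under any of the 10 groupings. With 10 splits the share cannot go under 0.1.

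Other splits also bear on genes and lists, and 10 splits are too few to exclude chance at any share under 0.05. For genes past the threshold the true count was 0, which all 10 splits reached, and the highest other was 5. For genes at an unadjusted p under 0.05 the true split gave 933, as large a count being reached in 1 split, and the highest other was 770. For lists called by camera at the preset correlation the true split gave 6, 9 of the 10 splits gave as many, and the highest other was 15, which points to differences between single libraries that move many genes together. With an estimated correlation 0 lists were called in each of the 10 splits.

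The lists with short transcripts were higher and those with long transcripts lower. With the length trend removed the oxidative phosphorylation median went from 0.29 to 0.18 (camera adjusted p = 1.2e-05). The ribosomal protein median went from 0.33 to 0.19 (adjusted p = 0.000568). Both kept their call and over 0.5 of their size, which met a bound written before this result against the trend as the whole cause. Those calls rest on the preset correlation, at which other splits also called lists. They therefore do not separate what remains from differences between single libraries. For PI3K-AKT-mTOR members the median went from -0.33 (quartiles -0.41 and -0.08) to -0.13 (-0.20 and 0.02, adjusted p = 0.0807), and for adhesion from -0.24 (-0.53 and -0.03) to -0.08 (-0.34 and -0.04, adjusted p = 0.0719), which is consistent with the trend as a cause, since both the calls and over 0.5 of the medians were lost. RAS-MAPK members went from -0.24 (-0.41 and -0.11) to -0.13 (-0.33 and 0.01, adjusted p = 0.0807), which decides nothing. Without shock wave replicate 3, oxidative phosphorylation (0.17, adjusted p = 0.000221) and PI3K-AKT-mTOR (-0.15, adjusted p = 0.00613) were still called. Their scores in the other 2 shock wave libraries were 0.17 and 0.09 and then -0.16 and -0.16. These lay beyond all 3 controls by more than the SD of the controls, so shock wave replicate 3 was not alone on that side. The bound that used these scores was rewritten after the results were seen. It therefore gives no test of that library as the whole cause. Ribosomal proteins (0.07, adjusted p = 0.0283), RAS-MAPK (-0.11, adjusted p = 0.0285) and adhesion (-0.12, adjusted p = 0.0258) were still called with less of their change, so for these that library and an effect of treatment cannot be told apart.

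The interferon response list did not follow transcript length, since with that trend removed its median was 0.36 (camera adjusted p = 1.3e-05). Shock wave replicate 1 alone is a candidate explanation. Without it the median went from 0.33 (quartiles 0.13 and 0.54) to 0.13 (-0.15 and 0.33) and the adjusted p was 0.102, with 1 library fewer. Of the 33 members, 9 lay above all controls in every shock wave tumour and 0 below. In both directions together, 16.4% of all tested genes separated the groups, and chance gives 10%. The members move together, with an estimated correlation of 0.524, so neither share is a test of the 9. The list score of shock wave replicate 3, -0.10, lay among those of the controls, -0.17 to 0.13. An effect of treatment that differs between tumours was not tested.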
